A study of Caenorhabditis elegans with 7 samples.

How the data were processed

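Small RNA was purified by gel excision from total RNA of Caenorhabditis elegans embryos, which had been released from adults with hypochlorite, and was sequenced on Illumina instruments, per the labels' protocols. The 7 libraries come from 5 genotypes in the N2 background. Wildtype and rnp-2(mg582) have 2 libraries each, 1 per experiment number in the sample titles. The genotypes mog-2(ok1221) and rnp-3(ok1424) have 1 library each, in experiment 1, and rnp-2(tm4058) has 1 library, in experiment 2. Nothing in the labels says whether libraries of a genotype came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

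The deposited table gives CPM (read counts scaled to the library total) at splice junctions, with an IEJ and an EEJ column per library. The labels do not expand these terms, and they are read here as intron-exon (unspliced) and exon-exon (spliced) junction. Each line is 1 end of an intron with its gene and the bases around the donor and acceptor sites. STAR and SAMtools are named in the submitters' processing notes, with no version or role. The genome build, the rules for reads that align to several places and the use of strand in counting are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies, such as F-box genes or the paralogs rnp-2 and rnp-3, can therefore not be told apart. The table as used here held 14533 lines with values, and 24 lines without values were not analysed here. Every line reached at least 0.505 CPM in some column, so junctions below about that level in every library are not listed, and sums over the table are not the depth of a library.

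Whole reads were recovered from the steps of the CPM values. All values of the 7 libraries (100% in each) were whole multiples of 1 step per library, within 1e-06 reads. The inverse of that step gave the library totals, which ran from 9901228 to 142819946 reads. Lines were joined into 7678 introns, 6855 of them with both ends listed and 823 with 1 end. Of the lines, 98.1% match an intron boundary of the WBcel235 annotation by chromosome, position and strand, and coordinates below are those of the table read as WBcel235, 1-based. Gene names in the table were matched to annotated genes by name (3172), older name (379) or position (156, among them a name that a spreadsheet had turned into a date), and 10 stayed unmatched. Introns of 1 gene whose spliced reads differed by at most 5% of the larger total, with at least 20 reads each, were counted once, because the same alignments appeared to be listed at several introns. This rule was set after a first fit on unmerged introns had been run. It turned 647 introns into 251 junctions and left 7282 junctions in 3717 genes. Spliced reads were summed over the junctions of a gene.

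The main test was limma 3.58.1 (trended empirical Bayes) on log2(scaled CPM + 0.5) with Benjamini-Hochberg adjustment, in R 4.3.3. CPM were scaled by TMM factors from edgeR 4.0.16, computed on spliced reads, so changes are relative to the bulk of the listed junctions and not to the whole library. At gene level the factors ran from 0.0846 in rnp-2(tm4058) to 2.97 in rnp-3(ok1424). The plan named log2(value + 0.5) for CPM and, separately, TMM as the main scaling with library size alone as the alternative. Applying TMM to the CPM was decided before any test was run, but after library totals and medians had been seen. On the other reading, with library size alone, no gene passes in rnp-2(mg582), and that count stands beside the main one in the results. Fold changes are on the log2(value + 0.5) scale, which understates changes of genes with low values. Genes and junctions were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 3551 genes and 6877 junctions. One fit had a coefficient per genotype over all 7 libraries. A second fit set the 5 mutant libraries against the 2 wildtype libraries. A genotype with 1 library has no replicate check of its own and is assumed to vary like those with 2. The plan also named edgeR's quasi-likelihood test for counts. It was run on the recovered reads as an alternative, because the unit is CPM, and DESeq2 1.42.0 was a further alternative. For the ratio of unspliced to spliced reads, limma on the difference of the log2 values took the place of the planned edgeR interaction test, which became the alternative. Levels below are scaled CPM of spliced reads unless stated, with mean ± SD.

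The genes named in the text follow a rule, and the gene lists are fixed ones. Both were set before the data were examined. The rule takes, among genes with a mean of at least 5 CPM, an adjusted p under 0.05 and no overlap between the groups' libraries, the 8 largest rises and the 8 largest falls. If fewer pass, it takes those that pass and then the genes of smallest p up to 4 per direction. To these it adds the mutated genes, 3 members of each gene list with at least 5 measured genes (the 2 with the highest mean and the 1 with the smallest p) and the 3 largest rises and falls of each lone library against the wildtype library of its experiment, among genes with a mean of at least 20 CPM. Other genes are said to have been chosen after their values were seen. The lists cover splicing factors, RNA interference factors, genes tied to ERGO-1 small RNAs, germline and maternal genes, spermatogenesis, muscle, intestine, neuron, collagen and cuticle, ribosomal protein, histone, F-box and MATH families, translation factors, zygotic cell fate, and heat shock and stress. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over 10 lists per comparison.

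Unspliced reads were summed over the listed ends of an intron, while spliced reads were counted once. A share of unspliced reads is therefore not the fraction of small RNAs from unspliced transcripts. The share of unspliced reads was compared by a two-sided exact permutation test over the 21 ways to choose 2 of 7 libraries, and each library's share has an exact (Clopper-Pearson) 95% interval. Such intervals, and floors of 3 reads for values of 0, cover counting error only, since reads without molecular identifiers are not independent molecules. Relations across introns used the Spearman correlation with 100000 permutations, adjusted over 12 relations in every setting. Donor and acceptor scores are sums of log-odds weights over the deposited bases, with weights taken from the listed introns that are annotated, have both ends listed, and start with GT and end with AG. Correlations between mutants used log2 ratios to a wildtype library over 222 genes with a mean of at least 5 CPM, and 50 simulations of unchanged libraries gave the value expected from a shared wildtype library. After the data were seen, direction was also compared between experiments. Genes with a log2 ratio of at least 1 in size in rnp-2(mg582) of 1 experiment were followed in a library of the other, each against its own wildtype library. The expected share was computed from the directions of all 222 genes. Introns were picked in the same way by a two-sided Fisher's exact test (adjusted p under 0.05), and introns with equal or undefined ratios were left out.

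The experiment number in the titles marks a shared experiment and so pairs the libraries. Over 3551 genes the deviations of replicate 1 from the genotype means of wildtype and rnp-2(mg582) had a correlation of 0.382. A fit with experiment as a block was an alternative, and its values stand beside a result where they change a call or move a count by more than 1.5 times. With a coefficient per genotype the blocked fit leaves 1 residual degree of freedom, against 2 in the main fit. Its spread, like that of the main fit, comes from wildtype and rnp-2(mg582) alone, so its counts are the less certain. Other alternatives were median-of-ratios size factors, library size alone, no filter, a minimum mean of 5 CPM, pseudocounts of 0.1 and 1, each library left out, and the 4 libraries of wildtype and rnp-2(mg582) alone. Alternatives chosen after seeing the data were edgeR on recovered reads, unmerged introns, all introns summed, the top junction per gene, the rnp-2(tm4058) library left out, subsets of mutants, introns free of annotated exons, introns with mostly spliced reads, the 2 introns that add most in the rnp-2 libraries left out, each intron end on its own, and a block for the ratio. The procedures were tested on simulated reads before use. At a log2 change of 2, the gene test recovered 54.9% of changed genes for rnp-2(mg582) and 79.5% for the mutants together, and the junction test 22.7% and 53.6%. At a log2 change of 1 these shares were 5.62% and 13.3% for genes and 4.26% and 2.53% for junctions. For the mutants together the ratio test recovered 48 of 200 changed introns at a log2 change of 2, and edgeR's interaction test 101 of 200. For rnp-2(mg582) the ratio tests were not simulated. Tables were handled in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.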

Results

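Small RNA from Caenorhabditis elegans embryos was sequenced to ask how mutations in splicing proteins change the small RNAs made against spliced and unspliced transcripts. The 7 libraries were 2 of wildtype, 2 of rnp-2(mg582) and 1 each of rnp-2(tm4058), mog-2(ok1221) and rnp-3(ok1424). As background, rnp-2 encodes a protein like component A of the U1 snRNP, and rnp-3 and mog-2 encode proteins like components B'' and A' of the U2 snRNP. Experiment 1 held wildtype 1 (20830155 reads), rnp-2(mg582) 1 (14573903), mog-2(ok1221) (13068321) and rnp-3(ok1424) (9901228). Experiment 2 held wildtype 2 (88364327 reads), rnp-2(mg582) 2 (93539047) and rnp-2(tm4058) (142819946). Spliced junction reads ran from 73843 in rnp-2(tm4058) to 474217 in wildtype 2, so precision was lowest in rnp-2(tm4058). Reads at the listed junctions, spliced and unspliced, were 1.54%, 1.33%, 1.94% and 2.03% of the experiment 1 libraries in the order above. In experiment 2 they were 0.578% of wildtype 2, 0.235% of rnp-2(mg582) 2 and 0.0564% of rnp-2(tm4058). Libraries of a genotype without a replicate carry no error of their own.

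**Figure D1:**
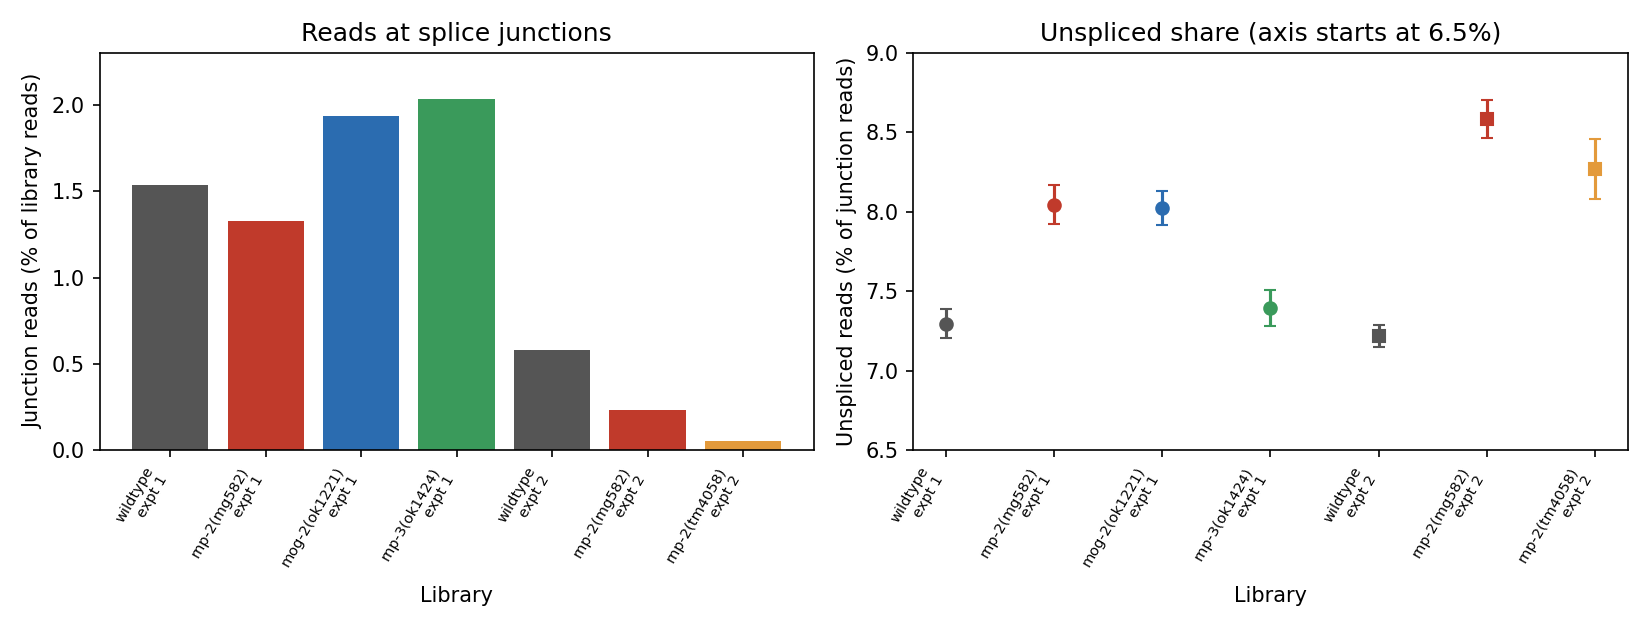
The left bars give reads at the listed junctions as a percentage of library reads, and the right points give unspliced reads as a percentage of junction reads with exact 95% intervals, on an axis that starts at 6.5%. Colours mark genotypes, circles experiment 1 and squares experiment 2, and the mutants lie between 7.39 and 8.58% against 7.30 and 7.22% in wildtype.

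The comparison of rnp-2(mg582) with wildtype asks at which genes small RNA reads across spliced junctions change when this U1 component is mutated. Small RNAs at spliced junctions of T20B3.1 (V:16815561-16820716) rose from 0.389 ± 0.0276 to 19.5 ± 1.42 scaled CPM (mean ± SD, n = 2 per group), a 22.5-fold change (log2 4.49 ± 0.25 SE). Those of F47G6.3 (I:1465597-1469593) rose from 0.208 ± 0.0520 to 15.0 ± 3.90. Those of B0001.5 (IV:12141165-12143331) fell from 25.9 ± 6.31 to 0.940 ± 0.178, 18.2-fold lower. Small RNAs of the homeobox gene ceh-82 (II:1732232-1733291) fell 11.4-fold, from 15.0 ± 3.51 to 0.847 ± 0.218. In each of these genes both mutant libraries lay outside the wildtype values, as the naming rule requires.

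The other large rises were in F55C9.3 (V:19287009-19288173), from 11.8 ± 2.28 to 135 ± 51.9 (10.7-fold), and its neighbour F55C9.5 (V:19290574-19293125), from 9.82 ± 1.17 to 82.7 ± 53.2 (7.21-fold). Y116A8B.1 rose 4.46-fold to 50.5 ± 7.74, Y116F11A.1 rose 4.44-fold (log2 2.15 ± 0.25 SE), the Wnt ligand gene cwn-1 rose 4.04-fold to 13.3 ± 3.47 and scrt-1 rose 4.02-fold to 10.3 ± 0.490. The other large falls were in K08F11.1, from 8.50 ± 2.09 to 0.412 ± 0.355 (10.1-fold lower), F52D2.12 (7.30-fold lower) and Y54G2A.19 (6.82-fold lower). An intron of K08F11.1 had a larger share of unspliced reads in rnp-2(mg582), given below. Its fall in spliced reads is therefore not a measure of all small RNAs of the gene. The gene dlk-1, which encodes a MAP3K of axon regeneration, fell 4.99-fold to 2.75 ± 1.78. CD4.8, among the most abundant genes here, fell 4.05-fold from 111 ± 14.7 to 28.3 ± 12.4, and the F-box gene fbxa-120 fell 3.87-fold. Adjusted p in limma for these 16 genes ran from 0.000402 (T20B3.1) to 0.0128 (fbxa-120). They are the 8 largest rises and the 8 largest falls of 20 and 23 genes that met the naming rule. At the mutated locus rnp-2 had 0.211 ± 0.0189 scaled CPM in wildtype and 0.344 ± 0.0609 in the mutant (adjusted p = 0.445), rnp-3 had 0.104 ± 0.00243 and 0.0463 ± 0.0198 (adjusted p = 0.509), and mog-2 was not analysed here.

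**Figure D2:**
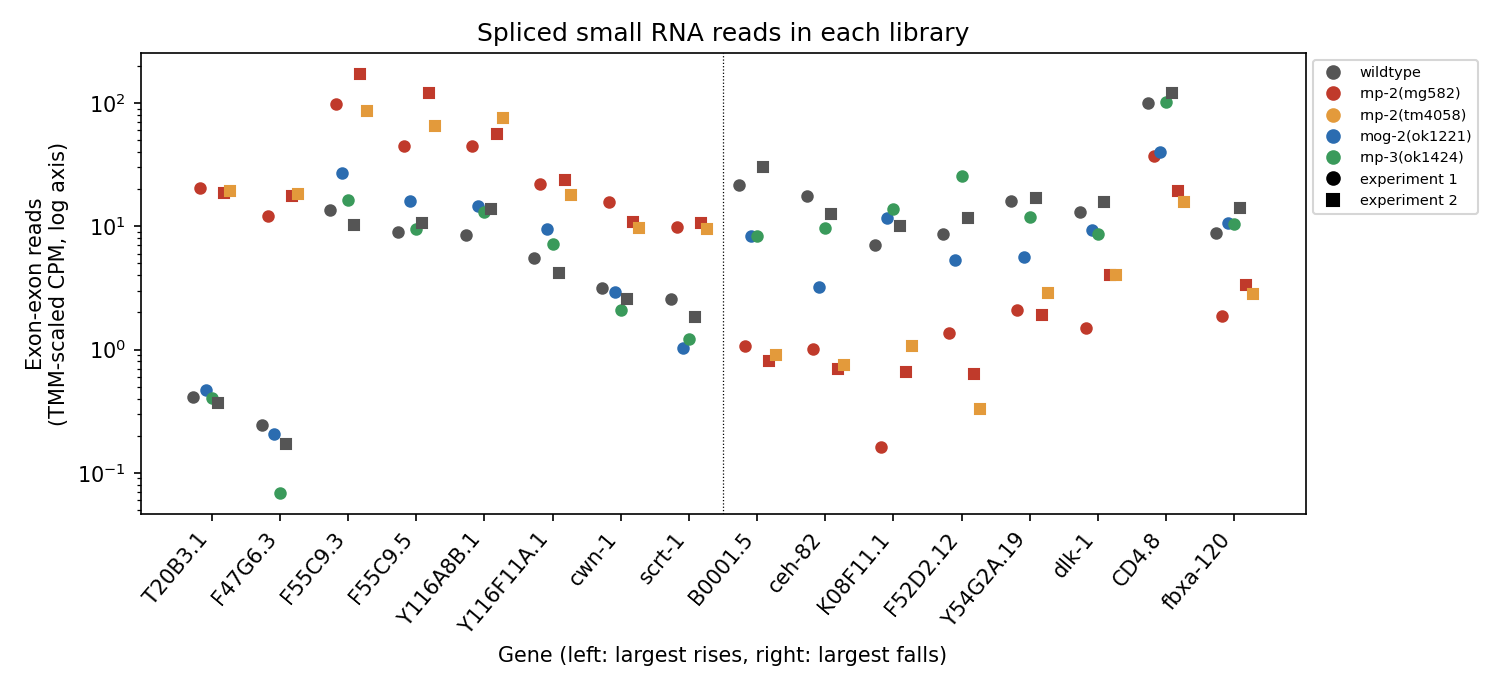
Points are single libraries, with scaled CPM of spliced reads on a log axis for the 8 largest rises (left) and 8 largest falls (right) in rnp-2(mg582), colours for genotypes, circles for experiment 1 and squares for experiment 2. T20B3.1 had a mean of 0.389 scaled CPM in wildtype and 19.5 in rnp-2(mg582), and B0001.5 had 25.9 and 0.940.

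In limma 297 of 3551 genes passed in rnp-2(mg582), 135 up and 162 down, and 775 had an unadjusted p under 0.05. edgeR on recovered reads called 326 genes, 284 of them shared. With library size alone in place of TMM, no gene passed in limma (93 at unadjusted p < 0.05), and the median log2 change of all genes was then -0.24. With experiment as a block 725 genes passed (301 up, 424 down), DESeq2 called 193, and 56 of 222 passed among genes with a mean of at least 5 CPM (29 up, 27 down). Without wildtype 1 only 1 gene passed, and it was not among the 297. Without rnp-2(mg582) 1, wildtype 2 or rnp-2(mg582) 2 the counts were 97 (64 up, 33 down), 105 (50 up, 55 down) and 141 (88 up, 53 down). Of the 16 largest changes none passed without wildtype 1, where adjusted p ran from 0.0537 to 0.160, and 12 each without rnp-2(mg582) 1 or wildtype 2, while cwn-1, dlk-1 and fbxa-120 were lost in both cases, scrt-1 in the first and CD4.8 in the second. Of these 16, leaving out a library moved the fold of 2 by more than 1.5 times. The log2 change of dlk-1 was -1.66 without rnp-2(mg582) 1 and -2.94 without rnp-2(mg582) 2, and that of F55C9.5 was 3.60 and 2.17. At junction level 394 of 6877 passed (182 up, 212 down), with none when library size alone was used (208 at unadjusted p < 0.05). The count was also 0 without wildtype 1, without rnp-2(mg582) 1 or without wildtype 2, and it was 70 without rnp-2(mg582) 2 (64 up, 6 down). Experiment as a block gave 1357 junctions (560 up, 797 down), edgeR 474 (240 up, 234 down), DESeq2 203 (110 up, 93 down), no filter 138 (88 up, 50 down) and a mean of at least 5 CPM 39 (21 up, 18 down), so which direction had more calls changed with the setting.

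Genes tied to ERGO-1 small RNAs moved both ways in rnp-2(mg582). Of 16 measured, 7 rose and 2 fell, and adjusted over the list alone 8 rose and 3 fell, while with experiment as a block 9 rose and 3 fell over all genes. Besides F55C9.3, F55C9.5 and Y116F11A.1, rises were found in C40A11.10 (6.91 ± 1.98 to 25.2 ± 0.792), K02E2.6 (0.498 ± 0.219 to 4.97 ± 1.28), C44B11.6 (0.0833 ± 0.0312 to 2.32 ± 0.769) and W04B5.1 (0.0810 ± 0.0586 to 1.45 ± 1.10), these 4 named after their values were seen. E01G4.5, a known source of these small RNAs, fell 3.23-fold from 186 ± 48.8 to 57.0 ± 14.4, and F39F10.4, named after its values were seen, fell from 7.12 ± 1.94 to 0.382 ± 0.327. The median log2 change of the list was 0.57 (0.31 with library size alone), with a camera adjusted p of 0.0189, an adjusted p of 0.652 with an estimated correlation and an adjusted p of 0.0824 in fry. Without wildtype 1 neither E01G4.5 (adjusted p = 0.0775) nor F55C9.3 (0.0775) passed, and E01G4.5 did not without wildtype 2 (0.0608).

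Of 40 measured RNA interference factors, 2 rose in rnp-2(mg582) and none fell, and the counts adjusted over the list alone were the same. The gene zfp-1, the AF10 homolog, rose 2.03-fold from 20.9 ± 1.94 to 42.9 ± 2.12 scaled CPM (adjusted p = 0.0137), a log2 change of 1.02 that was 0.33 with library size alone. The gene sid-2, needed for uptake of double-stranded RNA in the intestine, had 0 reads in wildtype and 79 in rnp-2(mg582), at least 51.3-fold higher against a floor of 3 reads over the wildtype group (adjusted p = 0.00203 in limma). The helicase gene eri-6 had 21.1 ± 2.02 and 14.8 ± 3.46 (adjusted p = 0.263), and it passed only with experiment as a block (0.0376). The list's median log2 was -0.11 and its mean 0.03, and camera gave an upward direction (adjusted p = 0.948). Left out, wildtype 1 ended the calls of zfp-1 (adjusted p = 0.165) and sid-2 (0.0775), and rnp-2(mg582) 1 (0.0691) or wildtype 2 (0.146) ended that of zfp-1. With experiment as a block 6 of these factors rose and 4 fell.

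Of 89 measured F-box and MATH family genes, 2 rose and 7 fell in rnp-2(mg582), and adjusted over the list alone 2 rose and 10 fell. The F-box gene fbxc-23 fell 4.01-fold from 5.37 ± 1.12 to 0.951 ± 0.0245, and fbxa-149, annotated as a pseudogene, fell 3.47-fold from 26.2 ± 3.35 to 7.36 ± 2.37. Those that rose, fbxa-46 (3.30-fold, log2 1.72 ± 0.31 SE) and fbxa-52 (0.0636 ± 0.00332 to 1.02 ± 0.479), were named after their values were seen. The most abundant member, bath-45, had 54.6 ± 0.698 and 48.4 ± 7.67 (adjusted p = 0.594). Camera gave the list an adjusted p of 0.201, with a median log2 of -0.11. Without wildtype 1 neither fbxc-23 (adjusted p = 0.108) nor fbxa-149 (0.128) passed, without rnp-2(mg582) 1 neither did (0.0680 and 0.0524), and without wildtype 2 fbxa-149 did not (0.0732). In the blocked fit 4 rose and 17 fell.

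Of 17 measured collagen and cuticle genes, 4 rose and none fell, and adjusted over the list alone 4 rose and 2 fell. These were cutl-7, cutl-15 (0.103 ± 0.0592 to 0.995 ± 0.128), col-45 (0.849 ± 0.364 to 2.55 ± 0.455) and col-60 (0.227 ± 0.0328 to 1.28 ± 0.753), the last 3 named after their values were seen. The gene cutl-7 had 1 read over both wildtype libraries and 27 over both mutant libraries (adjusted p = 0.00694). The most abundant members, col-71 (2.88 ± 0.234 and 1.32 ± 0.550) and col-111 (2.90 ± 1.62 and 1.18 ± 0.846), passed over all genes only with experiment as a block (adjusted p = 0.00319 and 0.000541). The median log2 of the list was 0.08 (camera adjusted p = 0.270) and -0.03 with library size alone. Of 23 ribosomal protein genes, none rose and 4 fell, with 6 falls adjusted over the list alone and 6 over all genes with experiment as a block, among them rpl-11.2 (0.515 ± 0.224 to 0.0312 ± 0.00153). The other 3 were rpl-31 (log2 -0.86 ± 0.19 SE), rpl-22 and rpl-23, named after their values were seen, and camera gave an adjusted p of 0.201. The calls of cutl-7 and rpl-11.2 ended without wildtype 1 (adjusted p = 0.111 and 0.0808). That of cutl-7 also ended without wildtype 2 (0.0613), and that of rpl-11.2 without rnp-2(mg582) 1 (0.140) or 2 (0.0874).

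None of 28 splicing factors, 28 germline and maternal genes, 6 histone genes, 15 translation factors or 20 heat shock and stress genes passed in limma, over all genes or adjusted over the list alone. For the splicing factors the U5 helicase gene snrp-200 had 1.75 ± 0.0464 and 2.89 ± 0.895 scaled CPM, the SR protein gene rsp-4 had 3.78 ± 0.493 and 3.02 ± 0.161, and the Sm protein gene snr-2 had 0.248 ± 0.00396 and 0.517 ± 0.0914. Germline members included the eggshell gene cbd-1 (log2 -0.23 ± 0.26 SE), the yolk receptor gene rme-2 (1.82 ± 0.0546 and 1.67 ± 0.0729) and meg-1, with 8 wildtype and 0 mutant reads. The histone gene hil-8 had 10.9 ± 0.970 and 11.3 ± 2.05. The translation factor iff-2 had 4.09 ± 1.22 and 4.31 ± 0.164, and sod-4, a superoxide dismutase gene, had 5.17 ± 0.882 and 8.38 ± 1.07. With experiment as a block hil-3 (adjusted p = 0.0132), pab-1 (0.00674), ife-5 (0.0201), sod-4 (0.0246) and dnj-7 (0.0116) passed. Markers of other tissues were few. Values of sperm genes (spe-41 log2 -1.43, adjusted p = 0.0147; spe-39 -0.01; spe-47 0.40), muscle genes (lev-11 -1.08, unc-60 -0.11), neuron genes (egl-21 0.53, ric-4 0.40, rab-3 -0.05, unc-10 -0.29) and zygotic genes (lin-12 0.56, hnd-1 -0.22) were not tested as lists, and no intestine gene of the list was measured.

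The comparison of all 5 mutant libraries with the 2 wildtype libraries asks what the splicing mutants share. Each library counted as 1 unit, and 3 of the 5 were rnp-2 libraries, 2 of them rnp-2(mg582). The mutant means therefore weigh rnp-2 most. The merlin homolog nfm-1 had 3.74 ± 1.73 scaled CPM in wildtype (n = 2) and 12.6 ± 3.02 in the mutants (n = 5). The gene zfp-1 had 20.9 ± 1.94 and 42.2 ± 3.98, and rde-11, which acts in amplification of secondary small RNAs, had 9.87 ± 1.96 and 21.4 ± 3.07. The ciliary kinesin gene osm-3 had 11.2 ± 3.55 and 3.33 ± 1.24, and cpin-1 had 11.4 ± 1.04 and 4.84 ± 1.57. Y116F11A.1 had 4.83 ± 0.926 and 16.1 ± 7.48, B0001.5 had 25.9 ± 6.31 and 3.91 ± 4.08, and ceh-82 had 15.0 ± 3.51 and 3.08 ± 3.87. In each of these 8 genes all mutant libraries lay on 1 side of both wildtype libraries, which was a condition of naming them. For zfp-1, rde-11, nfm-1 and Y116F11A.1 this held on scaled CPM but not as a share of all library reads. In rnp-2(tm4058) (142819946 library reads) they had 539, 295, 157 and 215 reads, against 1481, 854, 191 and 317 in wildtype 2 (88364327). For zfp-1, rnp-2(mg582) 2 (1373 of 93539047 reads) also lay below wildtype 2. For osm-3, cpin-1 and ceh-82 the share of some mutant library of experiment 1 lay above wildtype 2, though below wildtype 1. None of the 8 genes passed in limma, with adjusted p between 0.163 (nfm-1, zfp-1) and 0.284 (Y116F11A.1). In DESeq2 4 of the 8 passed, nfm-1 and zfp-1 (adjusted p = 0.00700 each), osm-3 (0.0203) and rde-11 (0.0207).

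No gene passed in limma for the mutants together (328 at unadjusted p < 0.05) or in edgeR (359 at unadjusted p < 0.05), while DESeq2 called 57 (39 up, 18 down). Without rnp-3(ok1424) 86 genes passed in limma (18 up, 68 down), among them nfm-1, zfp-1, B0001.5, ceh-82 and cpin-1. The 3 rnp-2 libraries alone gave 421 genes (157 up, 264 down), and the mog-2(ok1221) and rnp-3(ok1424) libraries together gave 6. At junction level 2 fell and none rose (621 at unadjusted p < 0.05), edgeR called none (669) and DESeq2 called 32 (22 up, 10 down). Both that fell lie in Y54E2A.4 and are named after their values were seen. The junction at II:14770136-14770196 had a log2 change of -2.03 ± 0.25 (adjusted p = 0.00836), and that at II:14759021-14760381 had -2.43 ± 0.34 (adjusted p = 0.0225). Y54E2A.4 as a gene had 3.82 and 8.77 scaled CPM in wildtype and between 0.381 and 1.33 in the 5 mutant libraries (adjusted p = 0.0705). The number of junctions was 81 without rnp-3(ok1424), 7 without mog-2(ok1221), 5 without wildtype 1, and 0 without wildtype 2 or without either rnp-2(mg582) library.

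Ribosomal protein genes were the 1 list that camera called in the mutants together with TMM scaling. With library size alone camera also called collagen and cuticle genes, upward (adjusted p = 0.0247, and 0.937 with an estimated correlation). The ribosomal protein genes had a median log2 change of -0.24 with TMM scaling (camera adjusted p = 0.00139, fry adjusted p = 0.0280), with adjusted p = 0.160 in camera with an estimated correlation. None of the 23 genes passed over all genes, and adjusted over the list alone 7 fell, or 4 with median-of-ratios size factors. With library size alone no member of any list passed in either comparison, over all genes or adjusted over the list alone. The fry call ended with experiment as a block (adjusted p = 0.0732). The gene rpl-11.2 had 60 wildtype reads and 4 reads in the 5 mutant libraries (adjusted p = 0.0705), and rpl-23 had 1.07 ± 0.184 and 0.345 ± 0.0946 scaled CPM. The other lists had no member past the threshold over all genes in limma. In DESeq2 rpl-11.2 (adjusted p = 0.00700), cutl-15 (0.000204) and F55C9.3 (0.0392) passed, as they did in limma without rnp-3(ok1424) (0.0225, 0.0417 and 0.0472). Adjusted over the list alone, zfp-1 (RNA interference) and cutl-15 (collagen and cuticle, 0.103 ± 0.0592 and 1.34 ± 0.727) were higher and hil-3 (histone, log2 -0.92 ± 0.23 SE) was lower. Genes tied to ERGO-1 small RNAs had a median log2 of 0.25 (camera adjusted p = 0.149), with log2 changes of 2.26 ± 0.74 SE for F55C9.3 and -1.23 ± 0.51 SE for E01G4.5. None of them passed adjusted over the list alone, but with experiment as a block F55C9.3, F55C9.5 and Y116F11A.1 rose and E01G4.5 and F39F10.4 fell on that measure (adjusted p from 0.0334 to 0.0485), and rde-11 rose among RNA interference factors (0.0498). Camera gave adjusted p of 0.0868 for splicing factors and for collagen and cuticle genes, and from 0.395 to 0.790 for the 6 lists that remain.

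The lone libraries show what each further genotype shares with rnp-2(mg582). In rnp-2(tm4058), F55C9.3 was 8.09-fold higher than in wildtype 2 (log2 3.02), F55C9.5 5.88-fold and Y116A8B.1 5.37-fold. These rises are relative to the bulk of the listed junctions. As a share of all library reads each of these genes was lower in rnp-2(tm4058). Of 142819946 reads there and 88364327 in wildtype 2, F55C9.3 had 1041 and 775, F55C9.5 786 and 808, and Y116A8B.1 921 and 1047. CD4.8 was 7.54-fold lower, E01G4.5 5.82-fold lower and fbxa-149 2.88-fold lower. In mog-2(ok1221), Y57G11C.51 was 3.54-fold higher than in wildtype 1, zfp-1 was at 45.1 against 22.3 scaled CPM and F55C9.3 was 1.97-fold higher, while CD4.8 was 2.47-fold lower, unc-10, which encodes a RIM protein of synapses, 2.42-fold lower and Y56A3A.33 1.71-fold lower. In rnp-3(ok1424), F43E2.1 was 1.87-fold higher, Y56A3A.33 1.80-fold and zfp-1 1.59-fold. The largest decreases on scaled CPM were 1.22-fold in Y53F4B.5, 1.21-fold in B0284.3 and 1.20-fold in Y37H9A.2. As a share of all library reads, each of these decreases was a slight increase. Of 9901228 reads in rnp-3(ok1424) and 20830155 in wildtype 1, Y53F4B.5 had 385 and 785, B0284.3 1513 and 3059, and Y37H9A.2 1556 and 3124. The fold values of the lone libraries compare 1 library with 1 library. In the limma fit against both wildtype libraries, adjusted p ran from 0.00784 to 0.0449 for the 6 changes in rnp-2(tm4058). It was 0.0423 for Y57G11C.51 in mog-2(ok1221), from 0.0523 to 0.316 for the other 5 genes named there, and from 0.199 to 0.713 for the 6 of rnp-3(ok1424).

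In limma, which lets each lone library vary like the replicated genotypes, 283 genes passed in rnp-2(tm4058) (128 up, 155 down), 77 in mog-2(ok1221) (36 up, 41 down) and 7 in rnp-3(ok1424) (6 up, 1 down). edgeR called 138 (88 up, 50 down), 115 and 5. With library size alone limma called 0, 2 and 2, and with experiment as a block 665, 537 and 151. In mog-2(ok1221) cdh-12 fell from 25.5 and 19.7 scaled CPM in wildtype to 3.64, xol-1 fell from 9.63 and 11.2 to 1.94, and ceh-20 rose from 4.92 and 5.77 to 21.9, these 3 named after their values were seen. The 7 genes of rnp-3(ok1424), named after their values were seen, were C04G2.10, which fell (log2 -2.93 ± 0.34, adjusted p = 0.0206), and AH9.1, R08B4.3, T14G8.4, bli-1, gfrp-1 and ugt-22, which rose. At junction level 232 (109 up, 123 down), 17 and 0 passed, with 681 at unadjusted p < 0.05 in rnp-3(ok1424). edgeR called 89 (69 up, 20 down), 31 and 4 junctions, library size alone gave 0, 3 and 0, the block gave 1140, 948 and 233, and median-of-ratios size factors gave 321, 81 and 8.

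Against rnp-2(mg582) itself, no gene differed in rnp-2(tm4058) in limma (360 at unadjusted p < 0.05), or 48 with experiment as a block. The counts were 208 in mog-2(ok1221) (572 with the block) and 263 in rnp-3(ok1424) (597 with the block). Sharing was also counted between experiments, so that no wildtype library is shared. Of 48 genes with a log2 ratio of at least 1 in either direction in rnp-2(mg582) 1, all 48 had the same direction in rnp-2(tm4058), where 50.2% was expected with no relation. Of 45 such genes of rnp-2(mg582) 2, 29 (64.4%, 47.7% expected) had the same direction in mog-2(ok1221) and 20 (44.4%, 47.9% expected) in rnp-3(ok1424). The median log2 change along the rnp-2(mg582) direction was 1.52, 0.38 and -0.03 in these libraries. Across 222 genes, which are not independent replicates, log2 ratios of rnp-2(mg582) 1 and rnp-2(tm4058), which share no wildtype library, had Pearson r = 0.895 and Spearman correlation = 0.827. Unchanged libraries simulated in the same way gave 0.00282. For rnp-2(mg582) 1 with mog-2(ok1221), which share wildtype 1, r was 0.346, below the simulated 0.499, with a covariance of 0.316 against 0.124. With rnp-3(ok1424) r was 0.135, and the covariance of 0.0780 was below the simulated 0.125.

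**Figure D3:**
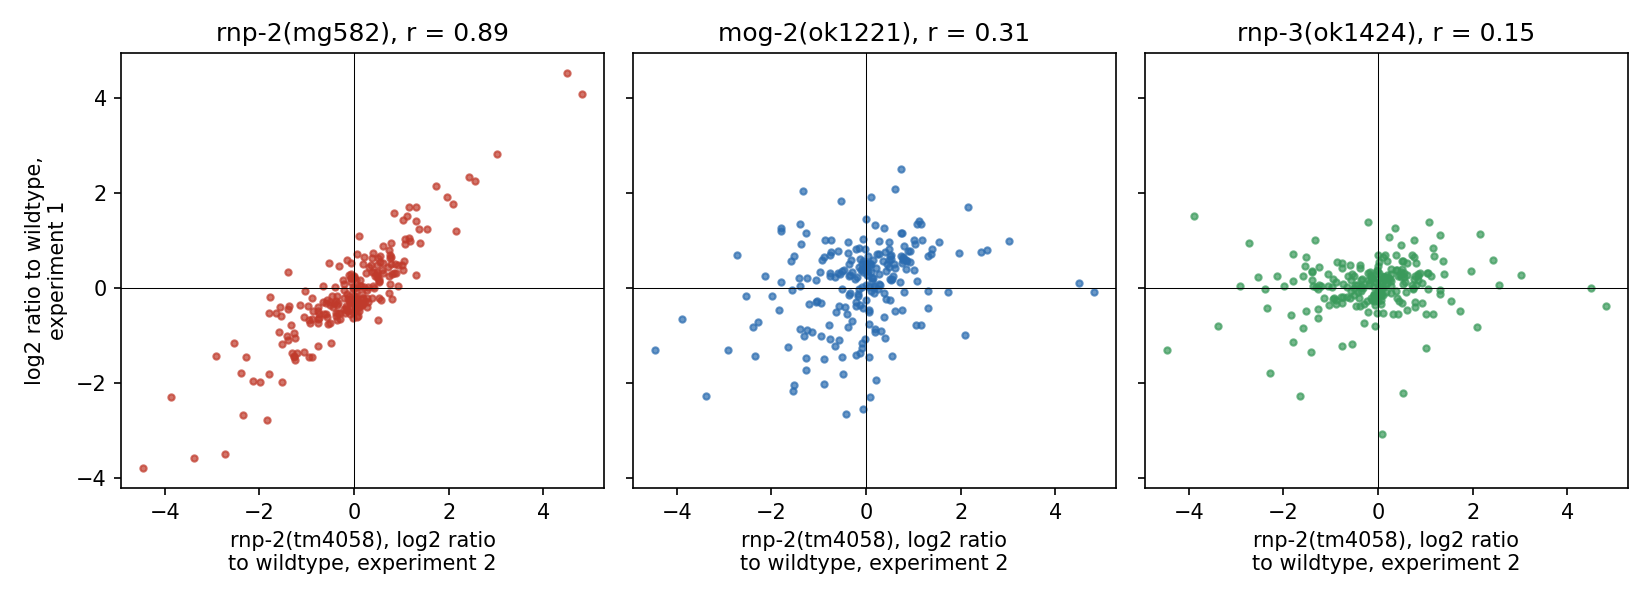
Each point is 1 of 222 genes, with the log2 ratio of rnp-2(tm4058) to wildtype 2 on the x axis and the log2 ratio of an experiment 1 mutant to wildtype 1 on the y axis. Pearson r was 0.895 for rnp-2(mg582), 0.306 for mog-2(ok1221) and 0.147 for rnp-3(ok1424), and the titles give it to 2 decimals.

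The share of unspliced reads among junction reads asks whether small RNAs made on unspliced transcripts are a larger part of junction reads in the mutants. It was 7.30% in wildtype 1 (exact 95% interval 7.21 to 7.39%) and 7.22% in wildtype 2 (7.15 to 7.29%). In experiment 1 it was 8.04% in rnp-2(mg582) 1 (7.92 to 8.17%), 8.02% in mog-2(ok1221) (7.92 to 8.13%) and 7.39% in rnp-3(ok1424) (7.28 to 7.51%). In experiment 2 it was 8.58% in rnp-2(mg582) 2 (8.47 to 8.70%) and 8.27% in rnp-2(tm4058) (8.08 to 8.46%). The mean was 8.06 ± 0.437% in the 5 mutant libraries and 7.26 ± 0.0557% in wildtype, a difference of 0.805 points. All 5 mutants lay above wildtype of their experiment, by 0.748, 0.726 and 0.0963 points in experiment 1 and by 1.37 and 1.05 points in experiment 2. A larger share did not mean more unspliced reads per library. Unspliced reads were 1121 CPM of all library reads in wildtype 1, 1068 in rnp-2(mg582) 1, 1553 in mog-2(ok1221) and 1503 in rnp-3(ok1424). In experiment 2 they were 417 in wildtype 2, 202 in rnp-2(mg582) 2 and 46.6 in rnp-2(tm4058). For the difference in mean share the two-sided exact permutation p was 0.0952, the smallest that 21 splits allow, and the test did not keep the experiments apart. The difference in the rnp-2 libraries was concentrated at 2 loci, a single listed end in fbxb-37 (II:2091953) and the B0250.8 intron at V:20470386-20470431. Together these added 0.658 points in rnp-2(mg582) 1, 1.09 points in rnp-2(mg582) 2 and 0.673 points in rnp-2(tm4058). Without both, the differences were 0.135, 0.654 and 0.0598 points in experiment 1 and 0.371 and 0.472 points in experiment 2, in the same order, and 0.346 points for the mutants together (exact permutation p = 0.0952). Unspliced reads were concentrated too, with 25.1% of them at 10 intron ends, among them ends in fbxc-43, fbxb-37, C09G1.3, eri-6 and B0250.8. Introns that overlap an annotated exon or have 1 end listed held 61.8% of them. Without these introns the difference was 0.633 points, and without introns where unspliced reads outnumber spliced reads it was 0.496 points (exact permutation p = 0.190 in both). Without the introns that overlap an exon or have 1 end listed, rnp-3(ok1424) at 3.14% lay below wildtype 1 at 3.24%. The other mutant libraries stayed above wildtype of their experiment. In introns with both ends listed, donor side reads alone gave 0.256 points (exact permutation p = 0.190) and acceptor side reads alone 0.173 points (exact permutation p = 0.571), with wildtype SDs of 0.219 and 0.321 points. Those SDs are the spread between the experiments, which these tests did not keep apart. The p-values therefore cannot decide whether the shares differed within experiments.

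For single introns the ratio of unspliced to spliced reads was tested in rnp-2(mg582), with the unspliced reads of both ends summed against 1 count of spliced reads. In B0250.8 (V:20470386-20470431, 46 bp) the unspliced share was 13.1% and 10.9% in the wildtype libraries and 41.9% and 32.6% in rnp-2(mg582), with 29.1% in rnp-2(tm4058) (log2 ratio 2.04 ± 0.28, adjusted p = 0.0112). In K08F11.1 (IV:4725023-4725069, 47 bp) it was 20.9% and 9.23% against 91.5% and 62.1%, and in osm-3 (IV:3797145-3797188, 44 bp) 3.45% and 3.21% against 20.5% and 24.1%. An intron of the mitofusin gene fzo-1 went from 0% and 9.52% to 85.2% and 91.3%. The ratio fell in daf-7, the TGF-beta ligand gene (54.5% and 14.3% to 4.65% and 0%), in Y66D12A.3 (33.3% and 35.9% to 5% and 2.44%) and in 2 introns of C24A1.3, both in 1 junction merged from 11 introns. Single shares rest on few reads in osm-3, fzo-1, daf-7 and Y66D12A.3, and introns were named after their values were seen.

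The ratio was tested only at introns with both ends listed whose unspliced reads passed filterByExpr, for which enough reads in 1 library sufficed. The counts therefore do not cover introns in general. In limma 44 of 347 introns passed, 28 up and 16 down, with 96 at unadjusted p < 0.05. The read ratio pooled over the libraries of a group, with no pseudocount, changed in the same direction in 33 of these (23 up, 10 down) and in the opposite direction in 5, namely 2 introns of E01G4.5 and 1 each of W03D8.7, T20B3.1 and Y65B4A.7. For the other 6, in Y43F8B.17, math-46, fbxa-149, F49F1.8, Y110A2AL.6 and Y92H12A.2, it could not be computed because a group had no spliced reads, so no change of ratio was measured. edgeR's interaction test called 34 (27 up, 7 down), and 16 rises and 4 falls were called by both tests, which include the introns above. The other rises called by both were in C53A5.13, T13C5.6, Y20F4.4, W03H9.2 (which overlaps an exon of the same strand), the ubiquitin ligase gene chn-1, T07E3.2, R04E5.9, Y105E8A.28, C04G2.10, W02B12.13, F08A8.5 and F43C1.5. With experiment as a block 134 introns passed. In the mutants together no intron passed in limma (36 at unadjusted p < 0.05) or in edgeR (29). The 23 rises with a higher pooled ratio had a median length of 46 bp, the 10 falls with a lower one 172 bp and the 303 introns not called 62 bp. Among those called by both tests it was 46.5 bp for the 16 rises and 172 bp for the 4 falls. Introns were also picked in 1 experiment by Fisher's exact test on reads of rnp-2(mg582) and wildtype, and followed in the other, so that no wildtype library is shared. Of 31 introns with a higher ratio in rnp-2(mg582) 1 and a decided direction in rnp-2(tm4058), 30 were higher there, against 51.9% of all introns. Of 34 with a higher ratio in rnp-2(mg582) 2, 23 (67.6%, 58.0% of all introns) were higher in mog-2(ok1221) and 16 (47.1%, 51.6% of all introns) in rnp-3(ok1424). Of introns picked for a lower ratio, 16 of 19 were lower in rnp-2(tm4058) (48.1% of all introns), 10 of 14 in mog-2(ok1221) (42.0%) and 10 of 14 in rnp-3(ok1424) (48.4%).

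Across 308 of the introns tested for it, the change in this ratio was related to intron length and splice site sequence, with introns not independent replicates. The change is signed, with positive values for more unspliced reads. Shorter introns had the more positive change in rnp-2(mg582) (Spearman correlation = -0.249, permutation p = 2e-05, adjusted 0.00012 over 12 relations) and in the mutants together (correlation = -0.250, p = 1e-05, the smallest that the permutations can give). Introns with lower donor scores had the more positive change too (correlation = -0.137, adjusted p = 0.0344, and -0.146, adjusted p = 0.0255 for the mutants). The relation with the acceptor score passed in the mutants (correlation = -0.173, adjusted p = 0.00884) and not in rnp-2(mg582) (correlation = -0.112, adjusted p = 0.0643), and the difference between these was not tested. With the change in ratio taken from edgeR, the relations were larger and all passed. In rnp-2(mg582) the correlation was then -0.309 with length, -0.259 with the donor score (adjusted p = 4e-05 each) and -0.156 with the acceptor score (adjusted p = 0.0106). In the mutants it was -0.272, -0.235 and -0.239 (adjusted p = 7.2e-05 or less). Changes in spliced reads across 6365 introns had weak relations. The Spearman correlation was 0.0361 with length in rnp-2(mg582) (adjusted p = 0.0115) and 0.0156 in the mutants (0.255), 0.0292 and 0.0273 with the acceptor score (0.0344 and 0.0430), and -0.00655 and 0.00193 with the donor score (0.656 and 0.880). Among the fewer introns with a mean of at least 5 CPM none of the 12 relations passed after the same adjustment (smallest adjusted p = 0.138).

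**Figure D4:**
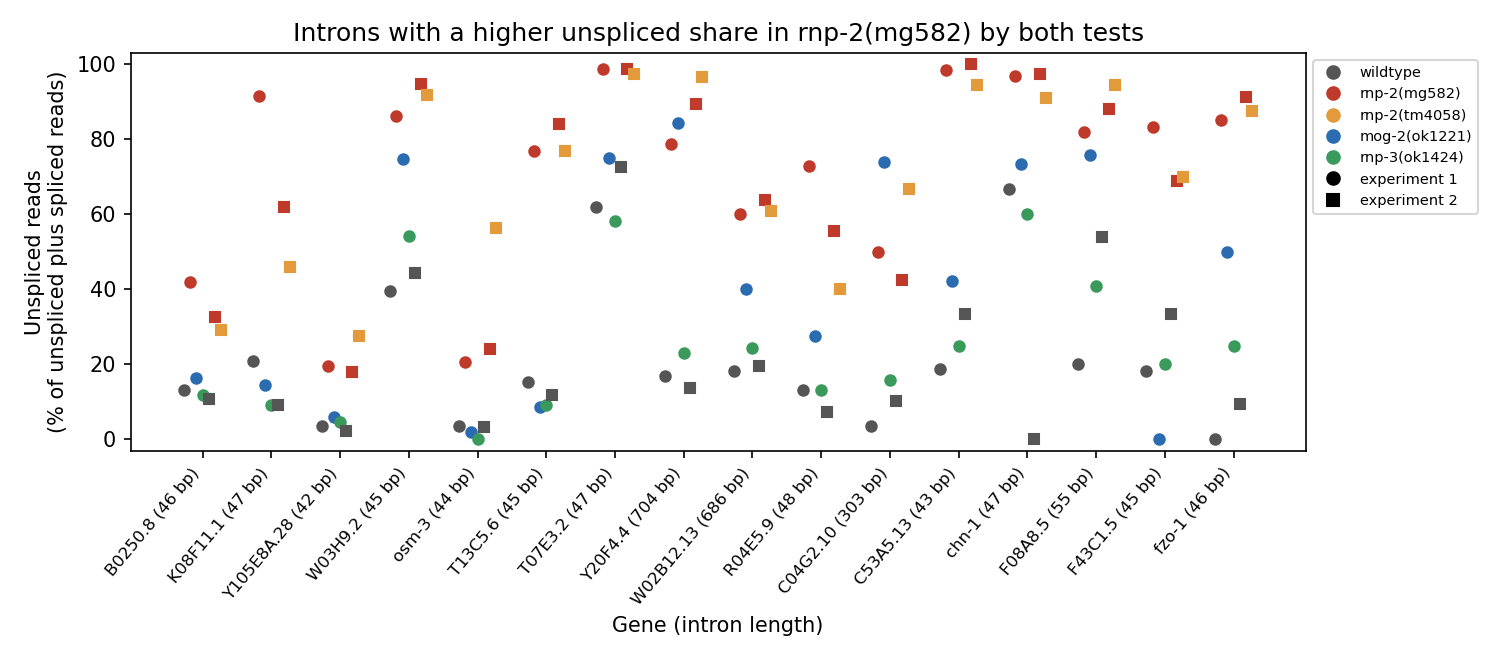
Points are single libraries, with unspliced reads as a percentage of unspliced plus spliced reads for the 16 introns with a higher ratio in rnp-2(mg582) by both tests, colours for genotypes, circles for experiment 1 and squares for experiment 2. In the B0250.8 intron of 46 bp the wildtype libraries had 13.1% and 10.9% and the rnp-2(mg582) libraries 41.9% and 32.6%.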

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

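The direct comparisons between mutant genotypes and the tests of explanations in this part were chosen only after the results were seen, while the correlations between mutants had been planned.

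A test of the difference itself called genes between libraries of different splicing mutants. In limma 208 genes (572 with experiment as a block) differed between mog-2(ok1221) and rnp-2(mg582), 263 (597) between rnp-3(ok1424) and rnp-2(mg582), and 428 (547) between the mean of both rnp-2 alleles and the mean of mog-2(ok1221) and rnp-3(ok1424) (187 higher and 241 lower in the rnp-2 alleles without the block). As mog-2(ok1221), rnp-3(ok1424) and rnp-2(tm4058) have 1 library each, a difference between libraries was not separated from a difference between genotypes.

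The rnp-2 libraries moved together. Chance values of shared wildtype libraries are argued against by r = 0.895 between rnp-2(mg582) 1 and rnp-2(tm4058), which share none, and few reads per gene by r = 0.888 among the 51 genes with a mean of at least 20 CPM. Grouping by experiment is argued against because log2 levels of rnp-2(mg582) 1 correlated at 0.932 or more with the rnp-2 libraries of experiment 2 and at 0.875 or less with libraries of its own experiment. A candidate explanation is a response to mutation of rnp-2 rather than to that of any splicing protein tested, since with experiment as a block 48 genes differed between the alleles and at least 572 between rnp-2(mg582) and the other mutants. This stays a hypothesis, because mog-2(ok1221), rnp-3(ok1424) and rnp-2(tm4058) have 1 library each, and neither embryo stage nor the strength of the alleles was tested.

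Some single libraries lay far from the other mutant libraries. Among the 5 mutant libraries, rnp-3(ok1424) stood apart with 9.75 scaled CPM of ceh-82 and 7.64 of cpin-1, and mog-2(ok1221) with 2.61 of cutl-15. In rnp-2(tm4058) both rpl-11.2 and fbxb-7 were at 0 reads. The other mutant libraries had 1 read each of rpl-11.2 and 4 each of fbxb-7, at most 0.0340 and 0.136 scaled CPM. Both lie below the 0.248 that 3 reads would be in rnp-2(tm4058), so these 2 values of 0 cannot be shown to lie apart. The other 3 came from 39 groups of values, and chance alone marks about 1 in 20.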

How the results depend on the processing

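Alternatives chosen only after the data were seen were edgeR on recovered reads, unmerged or summed introns, the top junction per gene, rnp-2(tm4058) left out, subsets of mutants, introns free of annotated exons, introns with mostly spliced reads, the share without 2 introns, single intron ends and a block for the ratio. The named genes of rnp-2(mg582) kept their direction and their side of the threshold in 649 of 731 alternative values, lost a call in 63, gained one in 8 and reversed in 11. The 16 largest changes kept their direction in all 272, and their calls in 232. For the mutants together 591 of 626 values stayed, 15 passed and 20 reversed. Counts and comparisons stayed in 79 of 145 alternatives. The cause of the shifts was not tested, except where fewer genes or libraries entered. Low reads limit rnp-2(tm4058) most. The median share per junction was 0 in every library, and gives no difference to compare.

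With library size alone, 0 genes and 0 junctions passed in rnp-2(mg582), 0 junctions in the mutants together, 0 genes and 0 junctions in rnp-2(tm4058), 2 genes and 3 junctions in mog-2(ok1221) and 2 genes in rnp-3(ok1424). The median log2 of all genes was then -0.24 in rnp-2(mg582), -0.96 in rnp-2(tm4058), 0.44 in mog-2(ok1221), 0.54 in rnp-3(ok1424) and -0.11 in the mutants together. With experiment as a block the genes were 725 in rnp-2(mg582), 665 in rnp-2(tm4058), 537 in mog-2(ok1221) and 151 in rnp-3(ok1424), the junctions 1357, 1140, 948 and 233, and the introns with a changed ratio 134. With a mean of at least 5 CPM, and fewer tested, rnp-2(mg582) had 56 genes and 39 junctions and the mutants 0 junctions. Without a filter rnp-2(mg582) had 138 junctions. DESeq2 called 193 genes and 203 junctions in rnp-2(mg582) and 57 genes and 32 junctions in the mutants. Median-of-ratios size factors gave 81 junctions in mog-2(ok1221) and 8 in rnp-3(ok1424). A pseudocount of 0.1 gave 1 junction in the mutants. edgeR called 0 junctions in the mutants, 138 genes and 89 junctions in rnp-2(tm4058), 31 junctions in mog-2(ok1221) and 4 in rnp-3(ok1424). The top junction per gene gave 3 genes in the mutants, the 3 rnp-2 libraries 421, and mog-2(ok1221) with rnp-3(ok1424) 6. Leaving out 1 wildtype or rnp-2(mg582) library gave 1 to 141 genes and 0 to 70 junctions in rnp-2(mg582), and leaving out rnp-2(tm4058) gave 298 and 438. For the mutants, any 1 library left out gave 0 to 86 genes and 0 to 81 junctions. With an estimated correlation camera called 0 lists in either comparison, and fry 0 in rnp-2(mg582).

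At a mean of at least 5 CPM, with fewer introns, no relation to sequence passed over 12 relations. The Spearman correlation of the ratio in rnp-2(mg582) and the mutants was then -0.127 and -0.177 with the donor score, -0.267 and -0.227 with length, and -0.240 with the acceptor score in the mutants. For spliced reads it was 0.0896 with length in rnp-2(mg582), 0.150 and 0.108 with the acceptor score, and reversed to 0.0595 with the donor score in rnp-2(mg582). With edgeR the acceptor score in rnp-2(mg582) passed at -0.156. Against the wildtype library of the other experiment, rnp-3(ok1424) reversed to r = -0.0739 with rnp-2(mg582) 2 and -0.00398 with rnp-2(tm4058).

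Reversals of named genes were all in values that did not pass. In rnp-2(mg582) log2 became -0.62 for hil-8, -0.49 for iff-2 and -0.083 for dnj-24 with library size alone, and 0.16 for rme-2 and 0.10 for rpa-1 with the top junction. Leaving out 1 library gave -0.34 to 0.26 for rpa-1, -0.11 to 0.28 for hil-8, -0.32 to 0.035 for bath-45 and -0.15 to 0.39 for iff-2. In the mutants library size alone gave -0.061 for rnp-3, -0.027 for snrp-200, -0.67 for bath-45, -0.19 for iff-2, -0.048 for sod-4 and -0.22 for dnj-24. A pseudocount of 0.1 gave -0.11 for rnp-3, and the top junction gave 0.059 for cbd-1, 0.080 for rme-2 and 0.037 for col-71. Leaving out 1 library gave -0.088 to 0.066 for rnp-3, -0.16 to 0.15 for cbd-1, -0.50 to 0.0083 for col-71, -0.40 to 0.20 for rpa-1, -0.45 to 0.20 for hil-8, -0.078 to 0.13 for bath-45 and -0.042 to 0.51 for iff-2.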

Other observations

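The test of overlap with annotated exons was set before its result was seen, and the other tests of explanations in this part were chosen only after the results were seen.

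Unspliced reads of the 7 libraries together came from few places. Introns where unspliced reads outnumber spliced reads, 359 in number, held 71.5% of them. The end with the most was in the F-box gene fbxc-43 (II:4235469), with 5486 unspliced and 11 spliced reads over the 7 libraries. An end in eri-6 (I:4464959) had 3023 unspliced and 1422 spliced reads, and an end in K05C4.9 (I:14730661), which overlaps no annotated exon, had 2611 and 118. At introns with both ends listed, the donor side took 48.4 to 48.9% of the unspliced reads in experiment 1 and 41.6 to 43.8% in experiment 2. In this share the mutants differed from wildtype of their experiment by -0.110, -0.466 and -0.482 points in experiment 1 and by 1.01 and 2.23 points in experiment 2.

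In rnp-2(mg582) limma called 28 introns with a higher and 16 with a lower ratio of unspliced to spliced reads. Of these 44 calls, 5 went against the read ratio pooled over libraries, with no pseudocount, and 6 had no computable one. For the rises, reads of annotated exons over the intron are argued against, since 26 of the 28 overlap none, and 21 of the 23 with a higher pooled ratio. For calls shared by both tests the pooled ratio had a median log2 of 4.02 against a fitted 1.99 in 16 rises. In 4 falls, of which 2 share 1 junction, it was -4.63 against -1.82. These calls were selected by the count test, which takes the same reads without that pseudocount. A large pooled ratio in the same direction therefore followed from the selection, and is no separate test of the pseudocount. For calls by limma alone the pseudocount cannot be told apart. There the pooled ratio of the rises, computable in 10 of 12, had a median log2 of 1.10 against a fitted 1.38 and was lower in 3, and 16 of 28 rises shared by the count test leave a 95% interval of 37.2 to 75.5%. That of the falls, computable in 8 of 12, had -0.53 against -1.31 and was higher in 2. Alignments listed at several introns cannot be told apart for the falls, as 8 of the 10 with a lower pooled ratio stand alone (95% interval 44.4 to 97.5%). Less complete removal of some short introns when rnp-2 is mutated may account for part of the rises. Of 31 introns picked for a higher ratio in rnp-2(mg582) 1 against wildtype 1, 30 were higher in rnp-2(tm4058) against wildtype 2 (95% interval 83.3 to 99.9%), where 51.9% of all introns were, although splicing itself was not measured.

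Junction reads were a smaller share of libraries in experiment 2. The highest share there, 0.578% in wildtype 2, lay below the lowest in experiment 1, 1.33%, and wildtype 1 had 1.54%. The cause was not tested. Within experiments, the share relative to wildtype was 0.864 in rnp-2(mg582) 1, 0.407 in rnp-2(mg582) 2 and 0.0974 in rnp-2(tm4058), and it was 1.26 in mog-2(ok1221) and 1.32 in rnp-3(ok1424).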
